A study of Halobacterium salinarum NRC-1 with 50 samples.

How the data were processed

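Total RNA of Halobacterium salinarum NRC-1, a halophilic archaeon, was measured on 50 arrays of spotted probes read in 2 colours. The labels describe cultures kept without oxygen at 38 °C and entrained for 120 h to cycles of 12 h light and 12 h dark at 150 µE per square metre per second. Samples came from 25 time points between 1440 and 5760 min after entrainment, 180 min apart, and the labels describe each sampling as made in the light. Each time point was hybridised on 2 arrays against a common reference, the sample of 3960 min. On replicate 1 the sample carried Alexa 594 and the reference Alexa 660, and on replicate 2 the dyes were exchanged. The 2 arrays of a time point were therefore counted as 1 replicate and averaged before each fit. The labels do not say that time points came from separate cultures, so p-values measure the spread between time points only.

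The authors deposited linear intensity values per spot: the mean of the spot, the mean of the local background, the brightest pixel, and pixel numbers and background standard deviations, at a high and a low scanner gain, per the file headers. No background had been subtracted from these intensities. The deposited value table holds log10 ratios of the same arrays. Set against the scanner values in array row order, its columns correlated with the log10 ratio of Alexa 594 to Alexa 660 at a median r of 0.979, with a lowest r of 0.788, across spots. Its direction is thus Alexa 594 over Alexa 660 on each array, not turned for the dye exchange. Column medians ran from -0.275 to 0.0660, exact zeros filled 0 to 54.1% of a column, and how the authors centred the columns and wrote the zeros is unknown. The scanner, image software and normalization are not given in the sources used here.

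Each array held 10752 spots. The 8656 spots with a value in the deposited table on every array were used, and the other 2096 were left out. A probe was printed as 4 spots, and 2429 features with at least 1 used spot were tested. The table of probe annotation gave 1 gene symbol for 532 spots, several symbols for 0 and none for 10220, which names 133 of the tested features. The other 2296 features are unnamed here, and control spots could not be set apart from them. All 133 symbols are listed in the RefSeq table provided, which belongs to another strain, and 0 of their Entrez identifiers matched it, so no coordinates are given.

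Background was corrected with normexp at an offset of 50 and each array was normalized by loess in limma 3.58.1 under R 4.3.3. Log2 ratios were turned to sample over reference and averaged over spots and then over both arrays of a time point. Windows of 24 h held 8 time points each. The third was compared with the first by limma's moderated test, with the second window sharing the estimate of spread. A rhythm was tested by limma's moderated F-test of a cosine and a sine of 24 h, with a quadratic drift, over 25 time points. Peak times are in hours after entrainment modulo 24. A change of rhythm between windows was tested by the interaction of window with both harmonic terms. All p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and rhythmic members with a one-sided Fisher's exact test, which carried no information because the 1 rhythmic feature was in no list.

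Of 27 gene lists written before the data were examined, 9 had at least 3 measured members. The gene glmS, caught by the pattern for aminoacyl-tRNA synthetases, and panB, caught by that for the proteasome, were taken out of those lists afterwards because they do not belong there. The rule for named genes was also fixed beforehand. In the window comparison it takes the 12 strongest rises and 12 strongest falls past the threshold with the same sign in each dye orientation, in the rhythm the 24 largest amplitudes past the threshold with peak times at most 3 h apart between orientations, and where under 10 pass, the 10 with the smallest p. It further takes 5 genes for the interaction, up to 4 members of each described list, and a few genes of light sensing and fermentation. It was applied among features with a symbol, since only those can be named.

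A feature counted as above background where at least 50% of its spots exceeded the local background by 2 standard errors. By that measure 7.37 to 63.0% of the features of an array were above background in both dyes, with a median of 35.5%, and the brightest pixel was saturated in 0.298 to 4.20% of spots. The number of arrays and this low signal limit the precision. The fits were tested on simulated data with the residual spreads of the 2429 features and 200 changed features each. A window difference of 0.5 on the log2 scale was recovered in 80.0% of cases and a difference of 1 in 100%. A rhythm of amplitude 0.3 was recovered in 72.0% and of amplitude 0.6 in 98.0%. A rhythm of amplitude 1 held in the first window alone was recovered by the interaction test in 95.0%. Unchanged features were called as well, 15 for the window difference and 9 each for the rhythm and the interaction. Noise was drawn independently for each feature, and with 200 changes the adjusted threshold is looser than with few. These shares therefore do not carry over to a course with few changes.

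Array numbers in the labels fall into 3 series, with 12, 23 and 15 arrays, which also differ in which spots are empty in the deposited table. Of the 16 arrays of the first window, 10 belong to the first series, 2 to the second and 4 to the third. Of the 16 arrays of the third window, these numbers are 2, 5 and 9. The numbers of 1 array of 4320 min and both of 5580 min lie outside the run of their neighbours. So do those of 1 array each of 1440, 1620, 2520, 2700, 4680, 5220 and 5760 min, numbered between 4754 and 4761. A mislabelled array therefore cannot be excluded. All arrays were used as labelled. Alternatives fixed beforehand covered background correction, normalization, a filter on dim features, the deposited table, the median of spots, each dye orientation alone, fits of single arrays with time point and dye orientation as blocks, the array series, correlated residuals, time points left out, drift terms and other periods. Alternatives chosen after seeing the data used all spots, low-gain values for saturated spots, features above background, features with at least 2 spots, all 3 array series as terms, each series alone, the course without 2520 min and without 4320 and 5580 min, 1 array of each of these exchanged, and list members above background.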

Results

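The series followed the transcriptome of Halobacterium salinarum NRC-1 from 1440 to 5760 min after entrainment to light and dark cycles, at 25 time points 3 h apart, each measured on 2 arrays with exchanged dyes. The design allows a comparison of 24 h windows, which began at 1440, 2880 and 4320 min, and a test for a 24 h rhythm. The labels describe each sampling as made in the light and do not state outright whether light was constant over the course. Values are log2 ratios of a time point to the sample labelled 3960 min. Of 2429 features, 133 carried a gene symbol. The share of features above background in both dyes was lower early in the course, with a median of 19.3% on the arrays of the first window, 38.9% in the second and 51.3% in the third.

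Among the 44 features that passed between the third and the first 24 h window, 5 carried a gene symbol, nadC, sucD, arcC, cmk and purL, and all 5 were higher in the third. The largest rise among named genes was that of nadC, an enzyme of NAD synthesis, from -0.41 ± 0.30 (SD, n = 8) to 0.23 ± 0.22 (SD, n = 8), a difference of 0.64 ± 0.11 (SE) with an adjusted p of 0.00109. Its 8 values of the third window all lay above the mean of the first, as did all 8 of sucD, arcC and cmk and 7 of purL. The genes were called on the mean of these same values, so that these counts add no support. sucD, a subunit of succinyl-CoA ligase, rose by 0.53 ± 0.12 (SE, adjusted p = 0.0148), and arcC, the carbamate kinase of arginine fermentation, by 0.49 ± 0.12 (SE, adjusted p = 0.0303). The rises of cmk, cytidylate kinase, and of purL, an enzyme of purine synthesis, were 0.42 ± 0.10 and 0.41 ± 0.11 (SE), with adjusted p-values of 0.0325 and 0.0462. The level of purL in the first window rests on low signal, above background in the sample dye on 1 of 16 arrays there and on 14 of 16 in the third window. These 5 genes were higher in the third window in each dye orientation alone, but with the sample in Alexa 660 alone 0 features passed, and with Alexa 594 alone 34 passed, of the 5 genes nadC and purL.

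Among all features, 28 rose and 16 fell by limma's moderated test, 16 rose and 15 fell without background correction, and 380 had an unadjusted p under 0.05. No named gene fell past the threshold. The unnamed features with the largest rises, whose first spots are numbered 1849 and 2051, rose by 0.84 ± 0.14 and 0.69 ± 0.16 (SE). Those with the largest falls, numbered 4651 and 3887, fell by 0.99 ± 0.19 and 0.85 ± 0.22 (SE). Signal in the first window was low for some named genes. nadC was above background in the sample dye on 3 of 16 arrays there and on 13 of 16 in the third window, and cmk on 8 and 14. sucD and arcC were each above background on 13 arrays of the first window and 16 of the third.

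**Figure D1:**
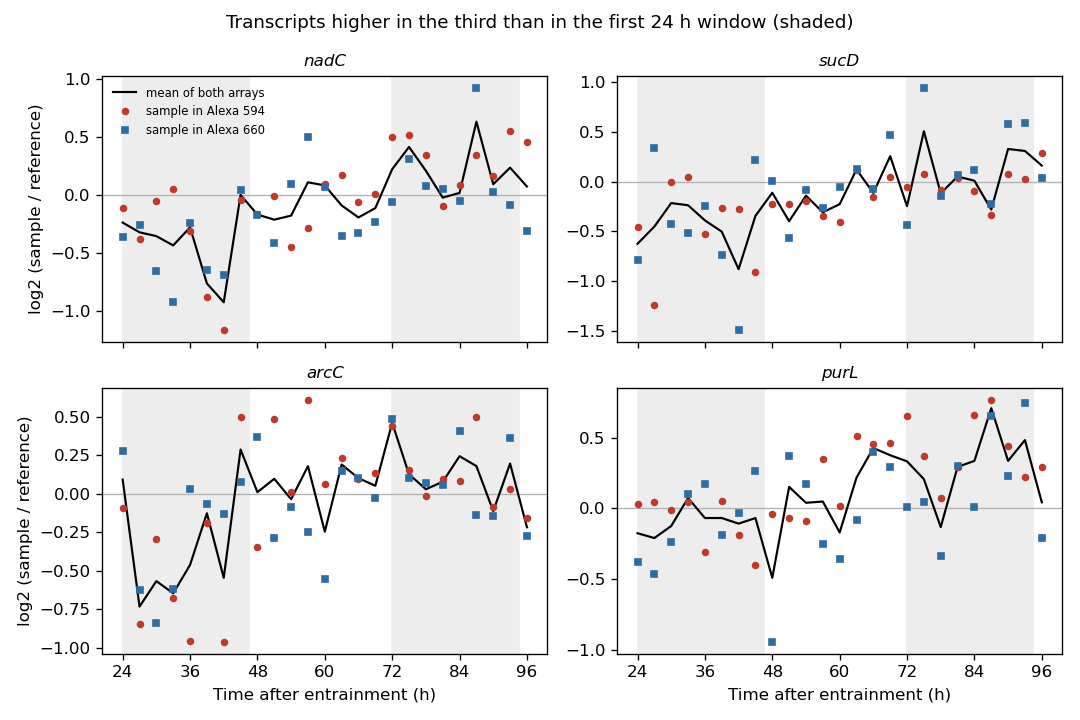
Log2 ratio of sample to reference (y axis) of nadC, sucD, arcC and purL against hours after entrainment (x axis); circles and squares are the arrays of each dye orientation, lines their mean, and shading marks the first and the third window. The third window lies above the first by 0.64 for nadC, 0.53 for sucD, 0.49 for arcC and 0.41 for purL.

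Of the 10 named genes with the smallest p in this comparison, 5 did not pass. lpdA, dihydrolipoamide dehydrogenase, differed by 0.43 ± 0.12 (SE, adjusted p = 0.0518) and glyA, serine hydroxymethyltransferase, by 0.43 ± 0.12 (SE, adjusted p = 0.0572), though by -0.38 within the second array series. hutU, urocanate hydratase of histidine breakdown, differed by 0.46 ± 0.13 (SE, adjusted p = 0.0572) and was above background on 1 of 16 arrays in the first window. gdhB, a glutamate dehydrogenase, was at 0.50 ± 0.16 (SE, adjusted p = 0.0937). purF, an enzyme of purine synthesis, was above background on 0 of 16 arrays in the first window and on 16 of 16 in the third, so that its difference has no measured lower level and is not given.

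Array series and window were partly tied. With the 3 series as terms in a fit of single arrays, nadC differed by 0.63 ± 0.13, sucD by 0.68 ± 0.15, arcC by 0.48 ± 0.14, cmk by 0.47 ± 0.12 and purL by 0.47 ± 0.13 (SE), and 64 features passed, 29 of them among the 44. With the share of arrays of the first series as a covariate of the averaged values, 6 features passed, and with the shares of the second and the third series 9, in each case with nadC as the only 1 of the 5 genes. With these shares nadC differed by 0.62 ± 0.14 (SE, adjusted p = 0.0404), while sucD at 0.62 ± 0.15, cmk at 0.46 ± 0.13, purL at 0.47 ± 0.14 and arcC at 0.40 ± 0.15 (SE) had adjusted p-values of 0.0532, 0.0679, 0.0880 and 0.167. Within the first, the second and the third series alone, nadC differed by 0.61, 0.56 and 0.59, sucD by 0.58, 0.77 and 0.64, arcC by 0.81, 0.13 and 0.47, and cmk by 0.37, 0.59 and 0.30. purL differed by 0.81 in the first series, 0.57 in the third and -0.17 in the second, where 4 features rose and 22 fell. None of these within-series values of the 5 genes passed the threshold. In the second series the first window held 2 arrays, of 2520 and 2700 min, both with the sample in Alexa 660. In the third series it held 4 arrays, all with the sample in Alexa 594. In the first series the third window held 2 arrays, of 4320 and 5580 min. The within-series values thus lean on the dye term and on few time points, and are not separate replications. With median centring in place of loess 1 feature passed, and leaving out 1620, 4320, 4680, 5040, 5400 or 5580 min left 26, 29, 28, 22, 17 or 25. Leaving out 1 time point ended the call of arcC for 6 of 24 points (1620, 1800, 1980, 4320, 5040 and 5580 min) and that of cmk for 7 (1620, 1980, 4320, 4500, 4680, 5040 and 5220 min). That of purL ended for 17 and held only without 1980, 2880, 3600, 3780, 3960, 4140 or 4680 min. The array numbers of 1 array of 4320 min and both of 5580 min lie outside the run of their neighbours. So do those of 1 array each of 1440, 1620, 2520, 2700, 4680, 5220 and 5760 min, which were not left out together. Without both 4320 and 5580 min 15 features passed, nadC and sucD among them and arcC, cmk and purL not. With 1 array of each exchanged, as the numbers would order them, 43 passed, purL no longer among them.

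None of the 9 gene lists passed in camera, 1 of them had an unadjusted p under 0.05, and 2 passed in fry. In purine and pyrimidine synthesis, 8 of 11 members had a positive difference, 1, purL, passed over all features. Adjusted over the list alone 2 passed, purL and purF, the latter with no array above background in the first window. guaB and purD differed by 0.20 ± 0.095 and 0.24 ± 0.12 (SE) without passing, purD with 1 of 16 arrays above background in the first window. The list had an adjusted p of 0.0611 in camera, 0.0880 with an estimated correlation and 0.00343 in fry, which asks only whether members move together in 1 direction. With the 8 members above background on at least 1 array of each window these were 0.0451, 0.133 and 0.0147, and the mean difference was 0.16. With all members its mean difference was 0.14, 0.14 with the array series as terms, 0.28, -0.082 and 0.14 within the first, the second and the third series, 0.073 with median centring and -0.069 in the deposited value table, where the median of all features shifted by -0.11. Of 12 aminoacyl-tRNA synthetases, 10 had a positive difference and 0 passed, over all features or adjusted over the list alone. leuS and ileS differed by 0.26 ± 0.11 and 0.29 ± 0.14 (SE), with 3 and 6 of 16 arrays above background in the first window. That list had an adjusted p of 0.295 in camera, 0.297 with an estimated correlation and 0.0171 in fry, and its mean difference was 0.095. That mean was 0.14, 0.071 and 0.0027 within the first, the second and the third series, 0.025 without background correction and -0.13 in the deposited value table. The other 7 lists had adjusted p-values of 0.418 to 0.964 in camera.

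In the tricarboxylic acid cycle, sucD alone of 6 members passed, also when adjusted over the list alone, and sucC, the other subunit of the same enzyme, named here after its value was seen, differed by 0.019 ± 0.10 (SE). In central carbon metabolism, eno, enolase, differed by 0.37 ± 0.13 (SE), which passed when adjusted over the list of 4 alone but not over all features (adjusted p = 0.127), and tpiA by -0.20 ± 0.11 (SE). The median difference of that list was -0.060 and its mean 0.012, and among the 3 rhodopsin genes these were -0.017 and 0.036, while camera gave both an upward direction. None of the 11 measured genes of chemotaxis and transducers passed by either adjustment, with htr6 at -0.20 ± 0.12 and htr2 at 0.16 ± 0.11 (SE). The sensory rhodopsin gene sop1 differed by 0.20 ± 0.11 and hop, for the light-driven chloride pump halorhodopsin, by -0.017 ± 0.10 (SE), without passing. sop2 and cbiQ were above background on 0 of 16 arrays in the first window and on 8 and 6 in the third, and their differences are not given. No member passed among 4 genes of DNA repair, where uvrB stood at -0.21 ± 0.090 (SE), 4 of cobalamin synthesis, where cbiG stood at 0.030 ± 0.15 (SE), or 3 of the proteasome, where pan1 stood at -0.22 ± 0.18 (SE). In the first window htr2 was above background on 1 of 16 arrays, sucC on 2 and eno on 4. arcA, arginine deiminase, of the same pathway as arcC, differed by -5.27e-05 ± 0.11 (SE).

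**Figure D2:**
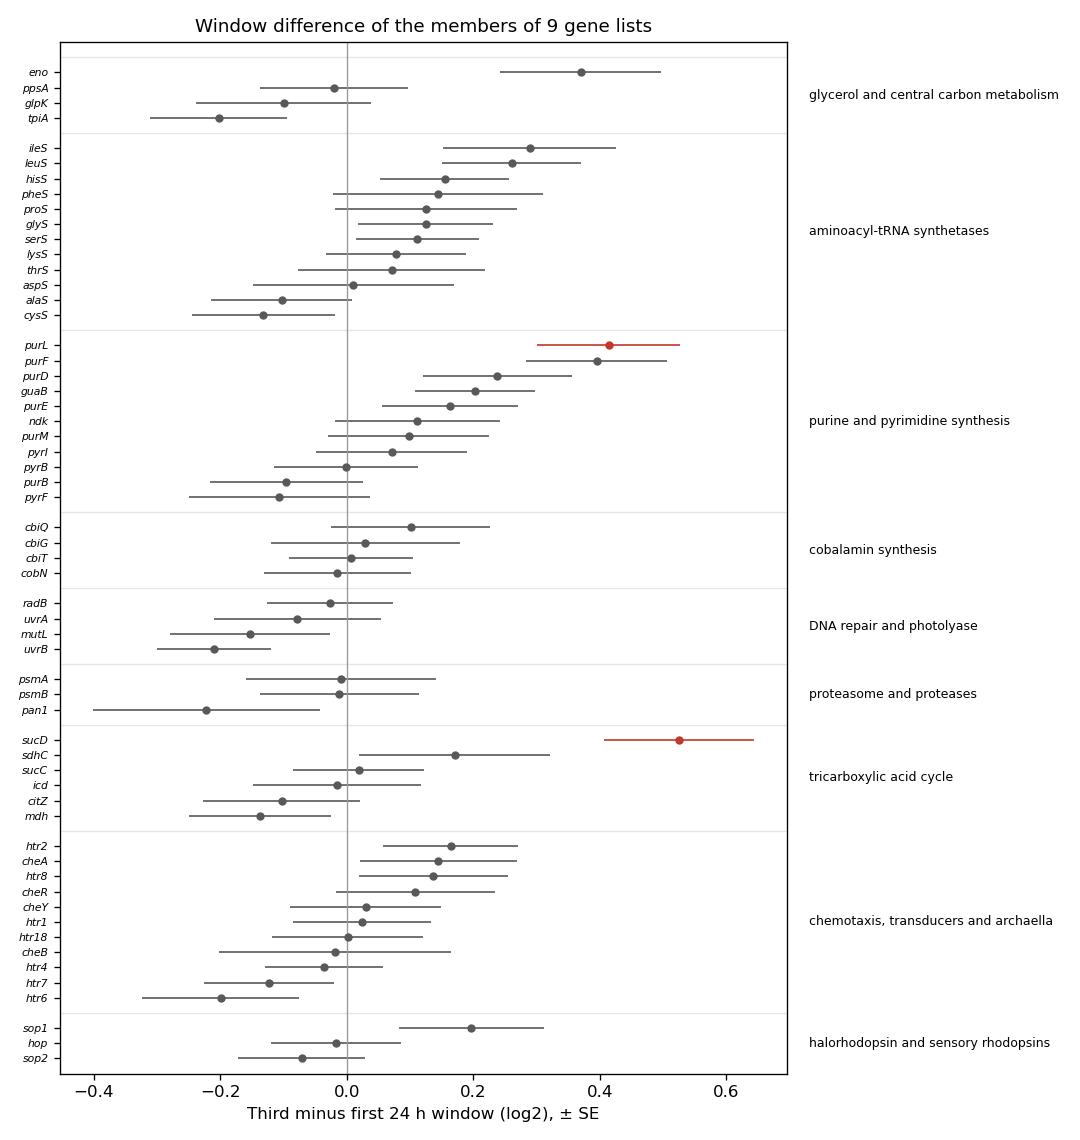
Difference of the third minus the first 24 h window in log2 with its SE (x axis) for each member of 9 gene lists (y axis); red marks members past the threshold over all features. Of these members, purL at 0.41 and sucD at 0.53 passed, while purF, purB, pyrF, sop2, htr18, cbiQ and glpK were above background on 0 of 16 arrays in the first window.

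In the test for a 24 h rhythm 1 gene passed the threshold. hisA, an enzyme of histidine synthesis, had an amplitude of 0.32 ± 0.056 (SE) with a peak 7.76 h into the cycle and an adjusted p of 0.0358 in limma's moderated F-test over 25 time points. It was above background in the sample dye on 4 of 16 arrays in the first window and on 9 of 16 in the third. Fitted alone, the arrays with the sample in Alexa 594 gave an amplitude of 0.38 and those with Alexa 660 gave 0.28, with peaks 2.15 h apart, and neither passed. The low values at 3780, 3960 and 4140 min came from Alexa 594 alone, at -1.48, -1.75 and -1.03. With Alexa 660 hisA stood at 0.33, -0.015 and 0.11 there. At 3960 min, where by the labels sample and reference were the same time point, hisA averaged -0.88. The call was lost without that point (amplitude 0.28, adjusted p = 0.167), and held in 9 of 25 fits that left out 1 point, those without 1440, 1620, 2160, 2340, 2700, 3600, 3780, 5220 or 5760 min. Over the alternatives tried the adjusted p ran from 0.00750 to 0.9997. In all, 116 features, 4.78% of those tested, had an unadjusted p under 0.05, about the share that chance alone gives.

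The other named genes with the smallest p did not pass. gyrB, a gyrase subunit, had an amplitude of 0.22 ± 0.057, map, methionine aminopeptidase, 0.22 ± 0.055, hutU 0.23 ± 0.059 and cysS 0.19 ± 0.058 (SE). hutI had an amplitude of 0.21 ± 0.071, cobN 0.17 ± 0.061, cheR 0.17 ± 0.069, ppsA 0.16 ± 0.064 and dcd 0.15 ± 0.058 (SE). In the first window gyrB, hutU and dcd were each above background in the sample dye on 1 of 16 arrays. There hutI and cheR were on 3, cysS on 4, map and cobN on 6 and ppsA on 15. The median amplitude of the 133 named genes was 0.090. Amplitudes of sop1, hop and arcA were 0.11 ± 0.066, 0.076 ± 0.060 and 0.068 ± 0.064 (SE). hisA belonged to none of the 9 lists, so that rhythmic members could not be compared between lists and other features, and within each list 0 members passed when adjusted over the list alone.

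**Figure D3:**
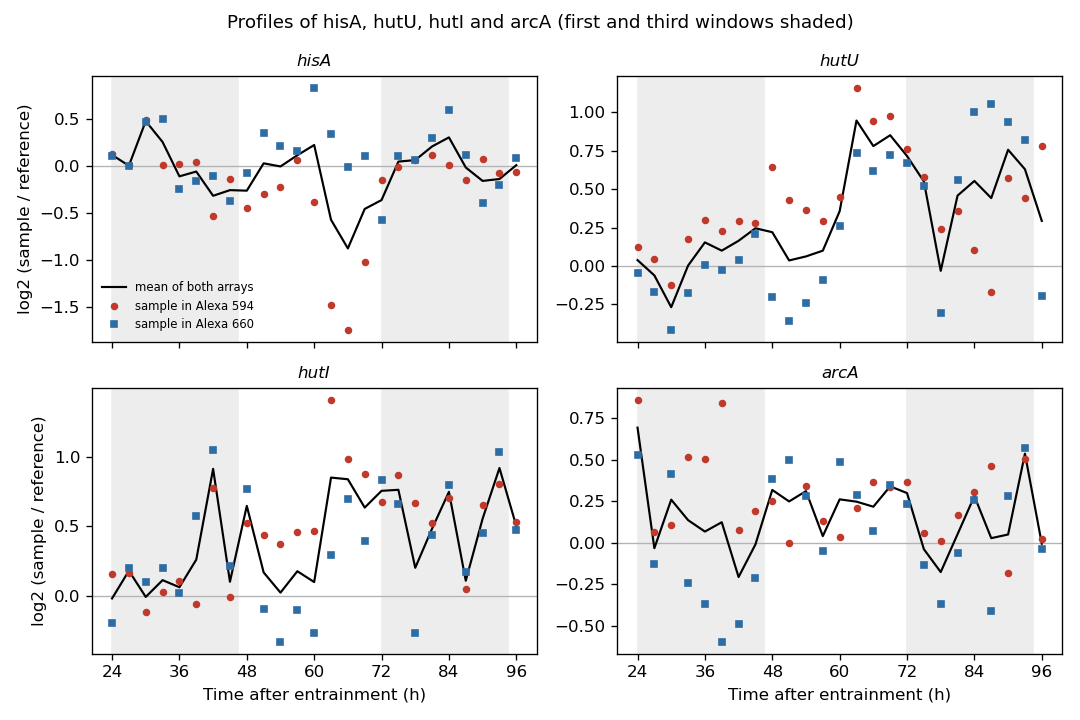
Log2 ratio of sample to reference (y axis) of hisA, hutU, hutI and arcA against hours after entrainment (x axis); circles and squares are the arrays of each dye orientation, lines their mean, and shading marks the first and the third window. At 3960 min, by the labels the time point of the reference, hutU averaged 0.78 and hutI 0.84.

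The rhythm differed between windows for 3 unnamed features and for no named gene, and 187 features had an unadjusted p under 0.05. The feature whose first spot is numbered 4495 had an amplitude of 1.20 in the first window, 0.068 in the second and 0.14 in the third (adjusted p = 0.0145). The named genes with the smallest p were citZ, citrate synthase, panB, folP, thrS and gyrA, none of which passed.

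By the labels, sample and reference were the same time point at 3960 min, where ratios other than 0 would then be error, although hutU and hutI stood above 0 on both arrays. The standard deviation over features of the dye-averaged log2 ratio was 0.24 there and 0.21 to 0.40 at the other time points, with a median of 0.26. The 95th percentile of its size was 0.48, against 0.44 to 0.80. Across features, which are not independent replicates, both arrays of a time point correlated at -0.11 to 0.17 after the sign was turned. The median of these correlations was 0.019. Arrays of the same dye orientation, each from another time point, correlated at a mean of 0.117, with a lowest value of -0.16. Arrays sharing a dye orientation were thus on average more alike than the arrays of a shared time point, which reproduced each other poorly. Agreement between the dye orientations had a median r of 0.012 over all features and -0.0080 over named genes.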

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

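The test of hisA by dye orientation and those of dye bias and of the reference RNA for hutU and hutI were chosen after values bearing on them were seen, as was the interval of the median for dye bias between windows; the other tests of explanations were set down before their results.

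The first pattern is the set of 44 features that differed between the third and the first window. Of 100 splits of the 16 time points only the real one gave as many, and the highest other gave 14. A share of 1 of 100 argues against a random split alone, but the splits take successive time points as exchangeable. Array series and signal also differ between the windows and would set the real split apart as well. A difference between array series as the whole cause is argued against only weakly. With the 3 series as terms these features kept a median of 1.02 of their difference, with quartiles of 0.91 and 1.14. But that fit leans on few arrays, 2 of the second series in the first window and 2 of the first series in the third. The latter 2 are arrays of 4320 and 5580 min whose numbers lie outside the run of their neighbours. Within the first, the second and the third series alone 0, 1 and 3 of the 44 passed, so that a contribution of the series stays open. A dye bias that stays constant over the course cancels, because both windows hold both orientations equally. Other dye effects were not decided. All 44 features had the same sign in each orientation, and the smaller difference was a median of 0.67 of the larger (95% interval of 0.51 to 0.75 with features taken as independent, lower quartile 0.40). But the features were called on the mean of both orientations, which favours both outcomes. With Alexa 660 alone 0 features passed, and with Alexa 594 alone 34, of which 18 were among the 44. Dimmer arrays in the first window were not decided as a cause. Of these features 63.6% were above background on at least 8 of its 16 arrays, against 21.5% of all features. This share is higher than the cause would give by the rule set beforehand. But its exact 95% interval of 47.8 to 77.6% reaches below the bound set for excluding the cause. The passage of time in the cultures, which the design names, was not separated from these.

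The second pattern is the rhythm of hisA, the 1 feature called rhythmic. Of 100 orders of the time points, the real one included, 3 gave as many, and the highest other count was 1. For a count of 1 this share says little more than the adjusted p of 0.0358 of the F-test. In that test 4.78% of all features had an unadjusted p under 0.05, about the share that chance alone gives, so that chance stays open. The ratio of amplitudes cannot decide on an artefact of 1 dye orientation: the smaller was 0.74 of the larger, with a standard error of 0.30. At 3780, 3960 and 4140 min hisA stood at -1.48, -1.75 and -1.03 with the sample in Alexa 594. With Alexa 660 it stood at 0.33, -0.015 and 0.11, so that these low values came from 1 orientation only. By the labels the ratio should be 0 at 3960 min. The call of hisA was lost without 3960 min (adjusted p = 0.167, against 0.00750 to 0.9997 over the alternatives). A biological rhythm of this gene stays open and was not tested apart from these arrays.

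The third pattern is that hutU and hutI, both of histidine breakdown, stood above 0 where by the labels sample and reference were the same time point, hutU at 0.94 and 0.62 and hutI at 0.98 and 0.69 with the sample in Alexa 594 and Alexa 660. Dye bias of 1 orientation cannot be judged from these values, since both genes were noticed for standing above 0 on both arrays. The smallest of the values was 2.18 times the SD over features on its array. High values were not peculiar to 3960 min. At 3780, 4140 and 4320 min hutU averaged 0.95, 0.85 and 0.72 and hutI 0.85, 0.63 and 0.75. Chance stays open: 8 features, 0.329% of all, lay as far from 0 in 1 direction on both arrays, but both genes were noticed for standing there. A reference RNA other than that of the 3960 min sample cannot be told apart from a local effect, since both arrays correlated at 0.11 across 792 features above background, too weak to show a common pattern and not low enough to exclude one. No biological explanation was tested.

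The rhythm differed between windows for 3 unnamed features, those with first spots 1605 and 4495 at an adjusted p of 0.0145 each and 1849 at 0.0380. Of 100 reassignments of windows within cycle positions only the real one gave as many, and the highest other count was 2. The reassignments take time points of different windows as exchangeable, although array series and signal differ between the windows.

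In the windows of 8 time points, a value was flagged by its gap to the nearest value as a share of the range. The cutoff has a nominal chance rate of about 1 in 20, which was not checked on these data. Single values were flagged in 17 of 192 examined combinations of 64 genes and 3 windows. In the first window these were hutI at 0.91, citZ at 0.66 and phoU at -0.26 at 2520 min, gyrB at 0.41 and htr6 at 0.93 at 1620 min, panB at -0.97 at 1980 min and mdh at -0.40 at 1440 min. In the second window they were dpsA at 1.24 and fer2 at 1.23 at 3240 min and arcA at 0.040 at 3420 min. In the third window they were hutU at -0.031 at 4680 min, cheR at -0.76 and gyrA at -0.38 at 5040 min, citZ at -0.39 and ileS at 0.88 at 5580 min, folP at -0.50 at 4500 min and cbiT at -0.65 at 4320 min.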

How the results depend on the processing

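The count of 44 features between the windows was within 1.5 times in 12 of 25 alternatives. It fell to 1 with median centring and to 1 in the deposited value table, to 6 and 9 with array series shares as covariates, and to 0, 26 and 7 within the first, the second and the third series. It rose to 72 with dye orientation as a replicate block and time point as a random block (arrays of 1 orientation correlated at a mean of 0.117, those of different orientations at 0.00959), to 70 with correlated residuals, to 78 with a linear slope and to 72 among features above background. The sample in Alexa 660 alone gave 0 and in Alexa 594 alone 34, leaving out single time points 17 to 54, and leaving out both 4320 and 5580 min 15. Similar counts did not always mean the same features. Among the 44 were 18 of the 34 in Alexa 594 alone and 21 of 31 without background correction. So were 28 of 41 with the median of spots, 36 of 78 with a linear slope and 1 of 26 within the second series. Low-gain values shared 40 of 46 and all spots 43 of 64. The series covariate raised the median standard error of the called features from 0.116 to 0.143 and kept a median of 0.994 of their difference. For other falls the cause was not tested. purL turned to -0.085 in the deposited value table and to -0.17 within the second series, where glyA, which had not passed, stood at -0.38.

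The 1 rhythmic feature was lost, to 0, in 22 of 30 alternatives and in 16 of 25 fits without a single time point. Among these were no background correction, median centring, the value table, the median of spots, either dye orientation alone, no or linear drift, each other period, either outer window left out, and the replicate block. Fits of another period ask for another rhythm, so that their 0 does not bear on the 24 h call. Of the 23 alternatives that fitted hisA at 24 h, 15 lost it. The interaction gave 0 with median centring and in the value table, 0 and 6 in each orientation alone and 5 with all spots, against 3. Lists past the threshold numbered 1 with the median of spots, 0 and 1 in each orientation alone, 2 in fry and 1 among members above background, against 0. The spread at 3960 min became 0.29 in the value table and 0.29 among features above background. All spots, low-gain values, features above background, features with at least 2 spots, all 3 series as terms, single series, the course without 2520 min or without 4320 and 5580 min, the exchanged arrays and list members above background were chosen after seeing the data. Low signal over background limits the early window most.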

Other observations

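Lists with fewer than 3 measured members were not tested as lists. Of their members, dpsA, a DNA-protecting ferritin-like protein, differed by -0.45 ± 0.20 (SE) between the third and the first window and phoU by 0.22 ± 0.10 (SE), the latter with 1 of 16 arrays above background in the first, and neither passed over all features. dnaK and dnaJ, chaperones, differed by -0.014 ± 0.14 and 0.055 ± 0.11 (SE). bat, a regulator of bacteriorhodopsin genes, differed by -0.12 ± 0.099 (SE) and nuoL, of the respiratory chain, by 0.13 ± 0.12 (SE).

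No gene list passed in camera, so that the count of splits with as many, necessarily 100 of 100, carries no information; the highest other count was 3.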
